A study of Mus musculus with 20 samples.

How the data were processed

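Hearts of 20 mice were profiled, with 1 oligonucleotide array per animal and 5 animals per group, per the labels. Per the labels' protocols, total RNA was extracted from frozen tissue, polyadenylated RNA was purified on oligo-dT resin, and biotin-labelled complementary RNA was made from it and fragmented. The deposited table gives a linear intensity for each of 12488 probe sets on each array. The software that made these values is not given in the sources used here. From the values, the authors' arrays share a trimmed mean of 1499.5 to 1499.6 with 2% left out at each end, and the deposited intensity ranged from 0.4 to 275790. No detection calls were used here.

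The probe set names are those of an Affymetrix murine array. Of the 12422 probe sets that are not controls, 10833 had a single gene symbol in the platform annotation, 396 had several and 1193 had none. Symbols were checked through gene identifiers against a RefSeq table of the assembly GRCm38.p6, which matched 10817 probe sets and changed 0 symbols; no coordinates were used. Probe sets with several or no symbols were tested and not named. A gene was represented by its tested probe set with the highest mean, and 909 genes had several.

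Values were taken as log2(intensity + 58), where 58 is the 10th percentile of all values, so that fold changes of dim probe sets are understated. The deposited scaling was kept, since array medians lay within 0.129 on the log2 scale, under the tolerance of 0.2. The 66 control probe sets and the dimmest 40% of the others were left out, leaving 7453 probe sets and 5663 named genes. Group means over all 20 arrays were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend and robust settings, 16 residual degrees of freedom). Adjusted p-values are two-sided and from Benjamini-Hochberg over the tested probe sets, with calls below 0.05. Comparisons were old against young controls, each supplement against old controls, and the supplements against each other.

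Before the data were examined, 33 gene lists, the tests, the alternatives and the rule for named genes were fixed; 30 lists had at least 5 tested genes, and 680 of their 849 symbols were on the array. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. None of the camera calls held with an estimated correlation. The named genes were the 8 highest and 8 lowest called changes per comparison, up to 3 called members of each list with a camera call or at least 3 called members, and 10 fixed genes, of which 9 were tested; where fewer than 5 genes passed, the 3 smallest p-values per direction would have been added. The text names part of this set.

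The position along the age change is minus the covariance of the supplement and age changes, corrected for noise in the shared old controls, divided by the noise-corrected variance of the age change. Its error came from leaving out each animal in turn. Unchanged supplements were simulated 1000 times by flipping the signs of residuals, and old controls were split 2 against 3 in 20 assignments. Array measures were compared by exact permutation tests, for which 5 against 5 arrays cannot go below 0.0079.

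The steps were tested on simulated data made from the means and spread of these arrays, with 200 of 7453 probe sets changed. In the simulated alpha-tocopherol comparison 22.0% of changes of 0.5 and 66.0% of changes of 1 (log2) were recovered, and 6.38% of the calls were false; in the simulated age comparison these were 42.0%, 83.0% and 3.10%. A position of 0 was estimated as -0.0037 and a position of 0.5 as 0.508, on average over 20 simulations. A list raised in a simulation was called, and 0 of the other lists were. The simulated genes varied independently of each other. In these data the estimated correlation was 0.24 for fatty acid oxidation genes and 0.32 for oxidative phosphorylation genes. The simulation therefore says nothing about false calls of lists with correlated genes.

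Alternatives were other pseudocounts, filters and scalings, no variance trend, array weights, fits of the compared groups alone, a replicate block, leaving out each animal, and, for lists, other tests. Added after seeing the data were 2 covariates, the hybridization control and 18S levels, the omission of young control 3 with old control 3, and that of old controls 1 and 4. For the closing tests 3 more gene lists were written after the first results were seen (liver markers, fasting and PPAR alpha targets, glucocorticoid targets), and their members already looked at were left out.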

Results

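Transcript levels were measured in hearts of male mice of a cross of the C57BL/6 and C3H strains. The labels give first-generation hybrids (F1), except for old controls 1 and 4, which are labelled hybrids without that mark. Without these samples, a setting chosen after seeing the data that leaves 3 old controls, 150 probe sets were called for age, 981 for alpha-tocopherol and 162 for both tocopherols, of which 147, 950 and 153 were also called with all samples. Each of the 20 animals gave 1 sample and 1 oligonucleotide array. The animals formed 4 groups of 5. Young controls were 5 months of age, and the other groups, all at 30 months, were old controls, mice fed 1000 mg/kg alpha-tocopherol, and mice fed alpha- and gamma-tocopherol at 500 mg/kg each. Both tocopherols are forms of vitamin E, and they differ by a methyl group on the ring. Supplemented diets began at 15 months of age. The comparisons ask how transcript levels differed with age, and how they differed in old animals given either supplement. Changes below are differences of log2(intensity + 58) ± standard error, with 5 animals per group. Adjusted p-values are from limma with Benjamini-Hochberg adjustment over 7453 tested probe sets. The number of arrays limits the precision: the median standard error of a difference was 0.179.

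**Figure D1:**
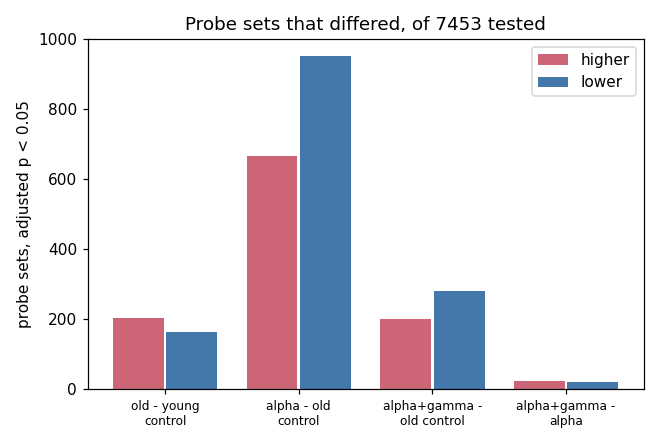
Bars show the number of probe sets (y axis, counts) with adjusted p below 0.05 in each comparison, separately for higher and lower levels in the first group named. The largest count was 953 lower probe sets in alpha-tocopherol hearts against old controls, and the smallest was 19 lower probe sets between the supplements.

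Old control hearts had lower levels of 14 of 28 tested fatty acid oxidation genes than young control hearts (camera adjusted p = 5.1e-17, and adjusted p = 0.068 with an estimated correlation). Among the largest single differences, Pdk4, a kinase that restrains pyruvate dehydrogenase, was lower by a log2 difference of -2.84 ± 0.29 (adjusted p = 1.8e-06, limma, Benjamini-Hochberg). The acyl-CoA thioesterase Acot1 differed by -2.26 ± 0.20, the mitochondrial carrier Ucp3 by -2.01 ± 0.19, the lipase inhibitor Angptl4 by -1.83 ± 0.14 and the lipid droplet protein Plin4 by -1.71 ± 0.18. In each of these genes all 5 old controls lay below all 5 young controls. Among genes higher in old hearts, the calcium-dependent kinase Camk2b rose by 1.48 ± 0.30, and Alas1, the first enzyme of heme synthesis, by 1.16 ± 0.10.

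In total 368 probe sets differed between old and young controls, 204 higher and 164 lower. In the fatty acid oxidation list 14 of 28 fell and 0 rose (21 and 2 adjusted over the list alone), with a median of -0.42 and the p-values given above. Its member Eci1, an enoyl-CoA isomerase, fell by 0.81 ± 0.11 on the log2 scale. Adipocyte markers also fell (2 of 11 genes, camera adjusted p = 0.0099, and adjusted p = 0.45 with an estimated correlation). The 2 called members were the lipases Pnpla2 (-1.13 ± 0.14) and Lipe (-0.91 ± 0.19), which also act in muscle. Adjusted over the list alone, 5 of these markers fell and 1 rose.

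Glycolysis and glucose uptake genes were higher, with 5 of 17 called (6 adjusted over the list alone). The camera adjusted p was 0.015, and adjusted p = 0.57 with an estimated correlation. Hexokinase Hk2 rose by 0.63 ± 0.12, the glucose transporter Slc2a4 by 0.50 ± 0.09 and phosphoglycerate kinase Pgk1 by 0.55 ± 0.11. Atrial markers were higher, with 2 of 7 genes called (4 adjusted over the list alone, camera adjusted p = 0.0045, and adjusted p = 0.45 with an estimated correlation). These were the myosin light chains Myl4 (0.63 ± 0.17) and Myl1 (0.85 ± 0.16), and Myl1 is not specific to atria. The natriuretic peptide Nppa, at 0.43 ± 0.13, did not pass the test (adjusted p = 0.063).

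Genes of the cytosolic ribosome fell in 4 of 22 cases (7 fell and 1 rose adjusted over the list alone). Their camera adjusted p was 1.6e-05, and adjusted p = 0.28 with an estimated correlation. Immediate early genes fell in 5 of 20 cases (6 adjusted over the list alone). Klf6 differed by -0.47 ± 0.11, Zfp36 by -0.58 ± 0.15 and Cebpb by -0.75 ± 0.21. The list had a camera adjusted p = 0.0021, and adjusted p = 0.45 with an estimated correlation. None of the 17 tested genes of the ER stress response was called, over all tested probe sets or adjusted over the list alone. As a list they lay lower (median -0.17, camera adjusted p = 0.041, and adjusted p = 0.57 with an estimated correlation).

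Further large age differences included the homeobox gene Meox2 (1.22 ± 0.26), the chemokine Ccl8 (1.14 ± 0.28), the endothelial and myeloid receptor Cd93 (1.19 ± 0.20), the mitochondrial ribosome subunit Mrps22 (1.19 ± 0.20) and the quinone reductase Cryz (1.34 ± 0.37). Sh3bgr rose by 1.27 ± 0.12, while 1 of its 2 other tested probe sets had the opposite sign. Metallothionein Mt2 (-1.44 ± 0.20), the transcription factor Zbtb16 (-1.47 ± 0.28) and the immunophilin Fkbp5 (-1.34 ± 0.38) fell. In the sarcomere list 3 of 16 genes fell and 0 rose, namely Myom2 (-0.95 ± 0.17), Des (-0.53 ± 0.14) and Tcap (-0.62 ± 0.18). Adjusted over the list alone, 4 fell and 2 rose. Slow myosin Myh7 fell by 1.02 ± 0.20 on the log2 scale. The basement membrane collagens Col15a1 (1.00 ± 0.22) and Col4a1 (0.84 ± 0.15) rose, as did the endothelial junction genes Pecam1 (0.65 ± 0.14) and Cldn5 (0.95 ± 0.23). In the endothelial list 2 of 16 rose and 1 fell (5 and 2 adjusted over the list alone). Neither the sarcomere nor the endothelial list passed camera (adjusted p = 0.11 and 0.20). Changes of Myh6 (0.18 ± 0.11), Nppb (-0.13 ± 0.26), Col1a1 (0.14 ± 0.18), Col3a1 (0.49 ± 0.26), Cdkn1a (-0.11 ± 0.23) and Gpx3 (-0.16 ± 0.13) did not pass the test. With array weights 731 probe sets were called. Without young control 3, which carried T cell transcripts, and old control 3, whose Gapdh 3' signal exceeded the 5' signal by 1.21 (log2), 361 were called, of which 273 were among the 368; this setting was chosen after seeing the data. The actin 3' to 5' difference of old control 3 was 0.23, within the range of the other old controls (0.081 to 0.29).

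**Figure D2:**
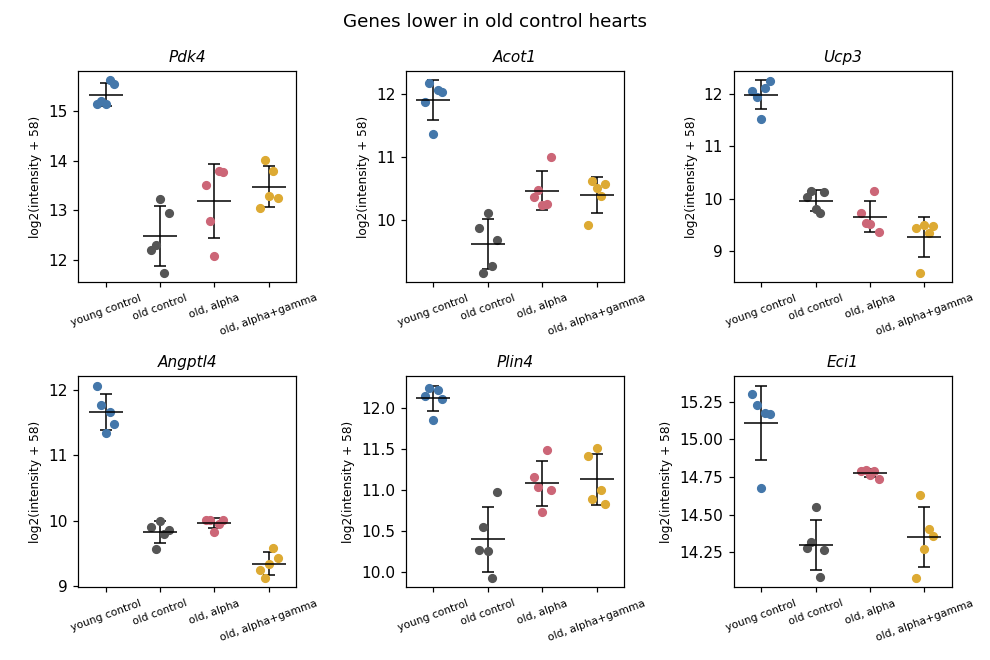
Points are single hearts, and bars are group means with SD (n = 5), of log2(intensity + 58) on the y axis for 6 genes in the 4 groups. For Pdk4 the mean was 15.3 in young controls, 12.5 in old controls, 13.2 with alpha-tocopherol and 13.5 with both tocopherols.

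Hearts of old mice fed alpha-tocopherol differed from old control hearts in single genes of many kinds. Superoxide dismutase Sod1 was higher by 2.40 ± 0.27 (adjusted p = 5.2e-06, limma, Benjamini-Hochberg), the kinase Uhmk1 by 2.61 ± 0.34 and Nipsnap2 by 2.06 ± 0.24. The collagen Col3a1 was lower (-1.39 ± 0.26), as was the DNA damage gene Gadd45a (-1.34 ± 0.25). Albumin (Alb), a liver product, differed by -4.71 ± 0.64, and the urinary protein gene Mup5 by -2.22 ± 0.44.

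In all 1619 probe sets differed, 666 higher and 953 lower. On the same arrays the bacterial hybridization controls, added to every sample, read 0.87 higher on the log2 scale with alpha-tocopherol. The 18S ribosomal RNA signal read 1.69 higher. For both, the 5 supplemented arrays lay above the 5 old controls (exact two-sided permutation p = 0.0079, the smallest this design allows, 0.016 after Benjamini-Hochberg adjustment). With the hybridization control level as a covariate 148 probe sets were called, and with the 18S level 161; both settings were chosen after seeing the data. Of 44 genes named here that the rule took for this comparison, 9 stayed called with the hybridization covariate, 15 with the 18S covariate and 6 with both. The 35 genes that lost their call with the hybridization covariate all kept their sign, with a median change of 0.881 times that without it (0.0463 to 1.36 times) and a median standard error 1.76 times as large. For the 29 lost with the 18S covariate, which also kept their sign, these were 0.901 (0.403 to 1.62) and 1.57 times. With the hybridization covariate Ccng1 was -0.73 ± 0.24, Lum -1.05 ± 0.28 and Hsp90b1 0.83 ± 0.29, no longer called (adjusted p = 0.11, 0.058 and 0.12). Others became smaller, among them Acvr1b (0.94 ± 0.80), Mup5 (-1.25 ± 0.74) and Cat (0.22 ± 0.20), also no longer called (adjusted p = 0.58, 0.39 and 0.61). The 18S covariate instead enlarged the changes of Acvr1b (3.06 ± 0.65) and Mup5 (-3.08 ± 0.66), which stayed called (limma adjusted p = 0.020 each). It left Cat at 0.43 ± 0.18, not called (limma adjusted p = 0.22). With the 18S covariate Sod1 was 1.09 ± 0.19, Nipsnap2 0.96 ± 0.22, Sdc4 0.74 ± 0.25 (adjusted p = 0.12, limma, Benjamini-Hochberg) and Uhmk1 1.21 ± 0.37 (adjusted p = 0.088), and these 4 stayed called with the hybridization covariate.

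Sarcomere genes were higher in alpha-tocopherol hearts, with 7 of 16 called higher and 1 lower, and the same numbers adjusted over the list alone. Their camera adjusted p was 0.0078, with adjusted p = 0.64 with an estimated correlation and 0.51 after quantile normalization. Myom2 (0.65 ± 0.17), the light chain Myl2 (0.50 ± 0.13) and Tcap (0.64 ± 0.18) rose, and Myh7 rose by 0.99 ± 0.20. With the hybridization covariate Myl2 was 0.02 ± 0.19 (adjusted p = 0.96, limma, Benjamini-Hochberg), while Myom2 (0.80 ± 0.29), Tcap (0.59 ± 0.31) and Myh7 (1.04 ± 0.36) kept changes of similar size and lost their calls with the larger error (adjusted p = 0.14, 0.33 and 0.12). Markers of other cell types moved on the same arrays. Fibroblast markers fell in 6 of 12 cases and rose in 1 (7 and 2 adjusted over the list alone, median -0.40), endothelial markers fell in 5 of 16 (6 adjusted over the list alone) and myeloid markers in 4 of 18 (5 adjusted over the list alone). Skeletal muscle markers rose in 3 of 9 cases, also adjusted over the list alone, namely the myogenic factor Myog (1.00 ± 0.30), the calcium buffer Pvalb (0.52 ± 0.16) and fast myosin Myh4 (0.71 ± 0.23). None of these 4 lists passed camera (adjusted p = 0.43, 0.14, 0.10 and 0.12). Of 61 oxidative phosphorylation genes 7 rose and 5 fell (7 and 4 adjusted over the list alone). The median was 0.10, the camera adjusted p = 0.033, and adjusted p = 0.79 with an estimated correlation. After quantile normalization the median was -0.04. The complex I subunit Ndufb8 rose by 0.63 ± 0.09 and the complex IV subunit Cox6b1 by 0.78 ± 0.14. ER stress genes were called higher in 6 of 17 cases and lower in 1, also adjusted over the list alone. Asns (0.59 ± 0.13) and the chaperones Hsp90b1 (0.73 ± 0.16) and Manf (0.93 ± 0.23) were among them (camera adjusted p = 0.033, and adjusted p = 0.64 with an estimated correlation). After quantile normalization this list was not called either (median 0.29, camera adjusted p = 0.071). With the 18S covariate the 3 lists, sarcomere, oxidative phosphorylation and ER stress, stayed called, and with the hybridization covariate they did not (medians 0.01, -0.16 and 0.18). They moved on arrays whose hybridization controls read 0.87 higher and whose 18S signal read 1.69 higher.

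Among antioxidant genes, 4 of 32 rose and 1 fell, with the same numbers adjusted over the list alone. The glutathione transferase Gstm1 rose by 0.77 ± 0.09 and catalase (Cat) by 0.43 ± 0.12, but the list did not pass camera (adjusted p = 0.089, and adjusted p = 0.64 with an estimated correlation). In the extracellular matrix list 11 of 38 fell and 2 rose (14 and 3 adjusted over the list alone), beside the fall of 6 of 12 fibroblast markers. Lum (-0.95 ± 0.16) fell, and Loxl1, a collagen cross-linking enzyme, rose by 1.34 ± 0.15. Col1a2 rose by 0.71 ± 0.11, though its other tested probe set had the opposite sign. Complement C1qb (-1.16 ± 0.22, with another probe set of opposite sign) and the myeloid lysozyme Lyz2 (-0.90 ± 0.26) fell. Of 30 proteasome genes 7 fell and 3 rose (9 and 3 adjusted over the list alone), including Psma4 (-0.80 ± 0.10) and Psmd6 (-0.55 ± 0.09). Psmb5 differed by -0.64 ± 0.09, with another probe set of opposite sign. The p53 list held 5 of 18 lower genes and 1 higher, the same adjusted over the list alone, among them Ccng1 (-0.78 ± 0.14). The matrix, proteasome and p53 lists did not pass camera (adjusted p = 0.11, 0.43 and 0.16). The clock genes Dbp (-1.34 ± 0.30) and Cry1 (0.76 ± 0.16) moved apart. The replication factor Pcna fell by 1.26 ± 0.16 on the log2 scale. Other large changes were those of the activin receptor Acvr1b (1.83 ± 0.47), the Z-disc protein Myoz1 (1.77 ± 0.40), the syndecan Sdc4 (1.72 ± 0.24), the protease Mep1b (1.65 ± 0.33), the kinase Tnk2 (-2.16 ± 0.29) and the biopterin enzyme Pts (-1.66 ± 0.16).

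**Figure D3:**
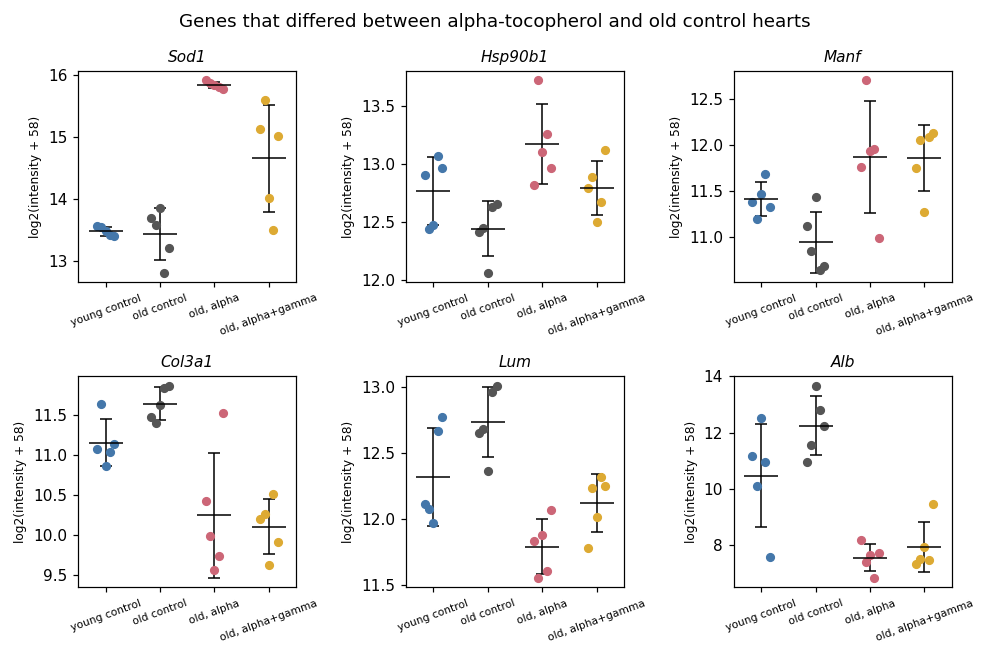
Points are single hearts, and bars are group means with SD (n = 5), of log2(intensity + 58) on the y axis for 6 genes in the 4 groups. For Sod1 the mean was 13.4 in old controls, 15.8 with alpha-tocopherol and 14.7 with both tocopherols.

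Hearts of mice fed both tocopherols differed from old controls in single genes, among them matrix genes that were lower or higher. Col3a1 differed by -1.54 ± 0.26 (adjusted p = 0.0015, limma, Benjamini-Hochberg), Col15a1 by -1.44 ± 0.22, the metalloproteinase inhibitor Timp2 by -0.89 ± 0.13 and the growth factor binding protein Igfbp6 by -1.71 ± 0.30. Loxl1 rose by 0.90 ± 0.15 and Col1a2 by 0.50 ± 0.11, the latter with another probe set of opposite sign. Col1a1, taken at its probe set with the highest mean (-0.31 ± 0.18), did not pass the test. The ER folding enzyme Pdia3 was higher by 1.37 ± 0.36, Gstm1 by 0.67 ± 0.09 and Sod1 by 1.22 ± 0.27. Alb differed by -4.33 ± 0.64 and Mup3 by -1.68 ± 0.36.

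A total of 479 probe sets differed, 199 higher and 280 lower. The hybridization controls read 0.29 higher than in old controls (exact permutation p = 0.16) and the 18S signal 0.53 higher (exact permutation p = 0.28). In hybridization controls animals 1 to 4 (13.082, 13.303, 13.154 and 13.132) lay above the highest old control (12.893). Animal 5 (12.363) lay below the lowest (12.515). In 18S animals 1, 2 and 5 (11.698, 11.96 and 11.889) lay above the highest old control (11.192). Animal 3 (10.701) lay within the range of old controls and animal 4 (9.796) below it. These p-values thus do not show that the group lacks the array difference seen with alpha-tocopherol. In the extracellular matrix list 9 of 38 genes fell and 2 rose (13 and 2 adjusted over the list alone). The median was -0.33, with camera adjusted p = 0.0015, and adjusted p = 0.62 with an estimated correlation. Of 17 ER stress genes 2 rose and 0 fell, also adjusted over the list alone (median 0.27, camera adjusted p = 0.0015, and adjusted p = 0.62 with an estimated correlation). These were Pdia3 and Manf (0.92 ± 0.23). Antioxidant genes rose in 3 of 32 cases (4 adjusted over the list alone), with camera adjusted p = 0.042, and adjusted p = 0.62 with an estimated correlation. Fibroblast markers fell in 2 of 12 cases and rose in 1 (6 and 1 adjusted over the list alone), with Dpt at -0.82 ± 0.20. The list had camera adjusted p = 0.042, and adjusted p = 0.62 with an estimated correlation. Atrial markers fell in 1 of 7 cases (2 adjusted over the list alone), the light chain Myl4 (-0.61 ± 0.17). Macrophage and myeloid markers held 0 called genes of 18, also adjusted over the list alone, with a median of -0.31. Both lists had camera adjusted p = 0.042, and adjusted p = 0.64 with an estimated correlation.

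Pdk4 rose by 1.00 ± 0.29 and Myh7 by 0.78 ± 0.20 with both tocopherols, whereas Ucp3, already lower with age, differed from old controls by a further -0.69 ± 0.19. With the hybridization control level as a covariate, chosen after seeing the data, 240 probe sets were called. Leaving out animal 1 of the group fed both tocopherols gave 263 calls, animal 2 gave 299, and leaving out old control 5 gave 300. Array weights called 858, of which 466 were among the 479.

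The supplements contain tocopherols that differ by a ring methyl group, at the same total dose of 1000 mg/kg. Alpha-tocopherol itself was given at 1000 mg/kg alone and at 500 mg/kg in the mixture. Its lower dose and the added gamma-tocopherol therefore cannot be told apart in this comparison. Between the supplements 42 probe sets differed, 23 higher and 19 lower with both tocopherols. Sod1 was lower with both tocopherols than with alpha-tocopherol alone (-1.18 ± 0.27, adjusted p = 0.042, limma, Benjamini-Hochberg). The collagen receptor Ddr2 (-1.75 ± 0.35), the receptor kinase Tyro3 (-1.54 ± 0.32), the galanin receptor Galr1 (-1.22 ± 0.26), the clock repressor Nr1d1 (-0.94 ± 0.18) and the ATP-gated channel P2rx7 (-0.60 ± 0.13) were also lower. Angptl4 was lower by a log2 difference of -0.62 ± 0.14, with 1 of its 2 other tested probe sets of opposite sign. The kinase Tnk2 (1.52 ± 0.29), the sialyltransferase St6galnac6 (0.93 ± 0.21), the ubiquitin ligase Mkrn1 (0.92 ± 0.20), Pcna (0.78 ± 0.16), Strap (0.73 ± 0.15), Psmb5 (0.50 ± 0.09) and Psmd6 (0.40 ± 0.09) were higher. So were the ribonuclease inhibitor Rnh1 (0.82 ± 0.18), Clip4 (0.72 ± 0.15) and Osbpl1a (0.57 ± 0.13, with another probe set of opposite sign), while Tmem250-ps was lower (-0.71 ± 0.15).

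Oxidative phosphorylation genes (median -0.08) and sarcomere genes (median -0.18) lay lower with both tocopherols, each with camera adjusted p = 0.0031, and adjusted p = 0.99 with an estimated correlation. None of the 61 and 16 genes was called over all tested probe sets; adjusted over the list alone 1 and 6 were lower. Proteasome genes lay higher, with 2 of 30 called (4 higher and 1 lower adjusted over the list alone). Antigen presentation (0 of 16 called, and 0 adjusted over the list alone) and ribosome genes (0 of 22, and 1 lower adjusted over the list alone) lay lower. These 3 lists had camera adjusted p = 0.047, and adjusted p = 0.99 with an estimated correlation. The hybridization controls (-0.57) and the 18S signal (-1.17) read lower with both tocopherols than with alpha-tocopherol (exact permutation p = 0.0079 each). For 85.2% of tested probe sets the 95% interval of the difference lay within 1 log2 unit of 0, and the median interval reached 0.372 to either side. The count was 0 when only these 10 arrays were fitted by limma, where 1071 probe sets had an unadjusted p below 0.05. It was also 0 with either covariate, where 827 (hybridization controls) and 594 (18S) had an unadjusted p below 0.05. Slopes of probe sets on the 18S level within groups correlated with this difference by -0.208, the direction that the lower 18S signal would give (one-sided permutation p = 0.014, 0.11 after Benjamini-Hochberg adjustment over 8 such tests, with the direction chosen after seeing the data), which leaves 18S open as a source. For the hybridization controls the correlation was 0.0360 (one-sided permutation p = 0.61). Leaving out an alpha-tocopherol animal gave 18 (animal 1), 41 (animal 2), 1 (animal 3), 13 (animal 4) or 1 (animal 5) calls. Leaving out an animal fed both tocopherols gave 24 (animal 1), 79 (animal 2), 3 (animal 3), 0 (animal 4, with 960 at an unadjusted p below 0.05) or 26 (animal 5) calls.

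**Figure D4:**
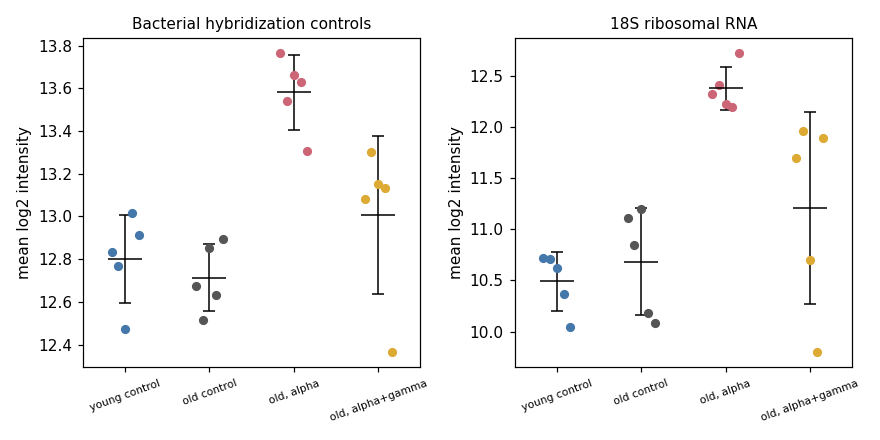
Points are arrays, and bars are group means with SD (n = 5), of the mean log2 intensity (y axis) of 9 bacterial hybridization control probe sets and of 3 probe sets for 18S ribosomal RNA. The alpha-tocopherol arrays averaged 13.6 and 12.4, against 12.7 and 10.7 in old controls.

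Along the age change, supplemented hearts lay away from old controls on the side of young controls. The position was expressed as a value of 0 at the old controls and 1 at the young controls, after correction for the old controls shared by both differences. It was 0.761 ± 0.132 with alpha-tocopherol and 0.555 ± 0.092 with both tocopherols (jackknife SE over animals). The 95% intervals were 0.502 to 1.02, which includes the value of 1, and 0.374 to 0.736. The position covers the age direction alone and is not a measure of likeness to young hearts. Along the first principal component, the direction of largest variance over arrays (19.5%), young and old controls averaged -11.9 and -16.4. Arrays with alpha-tocopherol averaged 20.8 and those with both tocopherols 7.55. The median correlation with young control arrays was 0.933 for old controls, 0.913 with alpha-tocopherol and 0.928 with both tocopherols. With the 18S covariate, chosen after seeing the data, the position with alpha-tocopherol was 0.534 ± 0.280, less than 2 standard errors above 0. The difference between the supplements was 0.206, with a 95% interval from -0.052 to 0.463. Among age-called probe sets chosen on a part of the old controls and set against the other part, a slope over these probe sets, which is another measure than the position, was 0.285 with alpha-tocopherol and 0.247 with both tocopherols.

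Of the 368 age-called probe sets, 300 had the opposite sign with alpha-tocopherol, 171 of them called, and 304 with both tocopherols, 109 of them called. Adjusted over the age-called list alone these were 199 and 172. With the same sign as the age change, 9 and 3 were called, or 13 and 5 adjusted over that list alone. The list was chosen on the same old controls and is not independent evidence. With the list chosen on a part of the old controls and tested on the other, a mean of 36.0 probe sets of opposite sign were called with alpha-tocopherol and 12.1 with both tocopherols. Uncorrected correlations with the age change over probe sets, which are not independent replicates, were -0.44 and -0.45. Simulated unchanged supplements gave means of -0.27 and -0.28, and 2.5% of simulations lay below -0.47 and -0.46, so that the correlations alone do not separate the supplements from no effect. The covariances, -0.066 and -0.054, lay below the corresponding simulated limits of -0.037 and -0.036.

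The changes with the supplements resembled each other, with a correlation over probe sets of 0.743. Simulated unchanged groups sharing the old controls gave a mean of 0.394. Their upper limit, cut at the same share of simulations as the limits above, was 0.683, not far below the real value. The covariance was 0.125, against 0.0210 simulated with shared controls. With the old controls split the correlation was 0.542 and the covariance 0.104, for which no simulated baseline was computed. Both supplements called 386 probe sets, 159 higher and 227 lower in both, where independent lists would share 17.8 and 35.8. These lists share the old controls, so that baseline is too low. With the old controls split, a mean of 68.5 were called by both, for which no baseline was computed. Splitting removes noise of shared arrays and would not remove an array difference common to both supplemented groups. On the first principal component alpha-tocopherol arrays lay 37.3 and arrays with both tocopherols 24.0 above old controls. Diet and such an array difference cannot be told apart here.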

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

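The tests of the hybridization controls, the 18S signal, noise shared through the old controls, an offset of the old controls and thymus RNA were chosen after the result they measure was seen, as were both covariates and the omitted samples. The splits were first counted with fits of the compared groups alone, and the fit over all 20 arrays was chosen after those counts were seen.

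More probe sets differed between alpha-tocopherol and old control hearts (1619) than between old and young controls (368). Among 100 of the 126 possible splits of the arrays compared, 1, the real grouping, called as many in each of these comparisons. The highest other count was 34 for alpha-tocopherol and 17 for age. This makes chance unlikely as the source, but 1 of 100 is the smallest share that these splits can give. Hybridization controls (0.87 higher) and 18S (1.69 higher) differed on the same arrays, but slopes of probe sets on these levels within groups correlated with the alpha-tocopherol change by only 0.0553 (one-sided permutation p = 0.32) and 0.147 (one-sided permutation p = 0.088), which neither excludes nor singles out hybridization or carried-over ribosomal RNA as a source. With the hybridization covariate Sod1 went from 2.40 ± 0.27 to 2.52 ± 0.47 and stayed called, while Col3a1 went from -1.39 ± 0.26 to -1.29 ± 0.47 (adjusted p = 0.14, limma, Benjamini-Hochberg), its call ending with the larger error; with the 18S covariate they were 1.09 ± 0.19 (called) and -1.40 ± 0.42 (adjusted p = 0.080). Both measures nearly follow the group, so diet, hybridization and RNA preparation cannot be told apart for these probe sets.

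Supplemented hearts lay on the side of young controls along the age change. Splitting the old controls so that no array enters both differences gave 0.762 ± 0.132 with alpha-tocopherol and 0.556 ± 0.092 with both tocopherols, which argues against noise in shared arrays as the whole source; averaged over assignments this is almost the same estimator as the corrected value and adds no independent evidence. Old and young controls differed by -0.087 in the hybridization controls (exact two-sided permutation p = 0.46) and by 0.19 in 18S (p = 0.51), and the old controls lay between young controls and supplemented arrays only in 18S, which leaves an offset of the old control arrays open. An effect of the supplements also stays open, since no further control group was measured here.

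Transcripts typical of liver or T cells read high in some control hearts. Over 29 liver genes not looked at before, the median was 0.59 higher in old controls than in alpha-tocopherol hearts, with 21 genes above 0. The 95% bootstrap interval was 0.20 to 0.89, drawn over genes, so it does not measure the spread between animals. Liver RNA in control samples would give such a difference, and the heart may itself express some of these genes. In young control 3 the T cell list exceeded the other young controls by a median of 3.60 (13 of 16 genes above 0), and the 3 Dntt probe sets (12.7 against 7.42, 10.8 against 7.82, 12.6 against 9.99), Cd3g (10.97 against 7.09) and a Rag1 probe set (13.2 against 6.17) were highest of all arrays, as thymus RNA would give; another Rag1 probe set (10.5 against 10.1) was not, which decides nothing, and since the test was chosen after this sample stood out, thymus RNA stays open. The sarcomere list in young control 3 differed by a median of -0.28 from the other young controls, with 0 of 16 genes above 0. The 95% bootstrap interval over genes was -0.32 to -0.20. A share of other RNA would give such a small common fall, and its size argues against a sample of another tissue under a wrong label. No biological explanation was tested for these transcripts.

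With both tocopherols 479 probe sets differed from old controls. Of 100 splits 1, the real grouping, called as many, and the highest other called 10, which makes chance unlikely as the source. Between the supplements the 42 calls were likewise reached by 1 of 100 splits, with 3 as the highest other, in the fit over all 20 arrays. With only the compared arrays fitted the real count was 0 (limma, 1071 at an unadjusted p below 0.05), which every split reaches, so that fit says nothing about chance. Since the fit over all arrays was chosen after that count was seen, the 42 calls rest on that choice.

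Single samples stood far from the other 4 of their group in 26 of 396 groups tested over 99 items, where chance gives about 1 in 20. The gap to the nearest sample, as a share of the group's range, is given for each. Among old controls it was 0.868 for Nppa (high in animal 5), 0.854 for Ccng1 (low in animal 4), 0.806 for St6galnac6 (low in animal 4), 0.746 for Col4a1 (high in animal 4), 0.805 for P2rx7 (high in animal 1) and 0.748 for C1qb (low in animal 3). The Gapdh 3' to 5' difference gave 0.970 in old control 3 (1.21 against a mean of -0.13 in the others) and 0.765 in animal 1 fed both tocopherols. Among young controls it was 0.784 for Eci1 (low in animal 3), 0.729 for Mrps22 (low in animal 4), 0.793 for Pnpla2 (high in animal 2) and 0.831 for Psmd6 (low in animal 5). With alpha-tocopherol it was 0.739 for Pecam1 (high in animal 4), 0.746 for Loxl1 and 0.736 for Psma4 (both low in animal 5), 0.803 for Col1a2 (high in animal 3) and 0.729 for Psmb5 (low in animal 3). With both tocopherols it was 0.833 for Ucp3, 0.801 for Myom2 and 0.816 for Ccng1 (all low in animal 2), 0.760 for Myh7 (high in animal 1), 0.772 for Pnpla2 (low in animal 3) and 0.855 for Gadd45a (low in animal 4). In animal 5 of that group it was 0.723 for Alb and 0.822 for Galr1 (both high) and 0.765 for the hybridization control level (low).

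The supplements differed in 18 named genes by the test of the difference itself (limma). The log2 difference, both tocopherols minus alpha-tocopherol, was -1.75 for Ddr2, -1.54 for Tyro3, -1.22 for Galr1, -1.18 for Sod1, -0.94 for Nr1d1, -0.71 for Tmem250-ps, -0.62 for Angptl4 and -0.60 for P2rx7. It was 1.52 for Tnk2, 0.93 for St6galnac6, 0.92 for Mkrn1, 0.82 for Rnh1, 0.78 for Pcna, 0.73 for Strap, 0.72 for Clip4, 0.57 for Osbpl1a, 0.50 for Psmb5 and 0.40 for Psmd6.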

How the results depend on the processing

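The covariates and the joint omissions of young control 3 with old control 3 and of old controls 1 and 4 were chosen after seeing the data. Array weights called 731 probe sets for age, 858 for both tocopherols and 7 between the supplements. The hybridization covariate called 148 (alpha-tocopherol), 240 (both) and 0 (between supplements), and the 18S covariate 161 (alpha-tocopherol) and 0 (between supplements). Between the supplements 11 were called with no filter, 64 with a stricter filter, 23 with median centring, 11 with no variance trend and 0 with only these arrays fitted. Without old controls 1 and 4, 150 (age), 981 (alpha-tocopherol) and 162 (both) were called, with fewer samples. The other settings with all samples kept these counts within 1.5 times. Leaving out an animal gave 258 to 367 calls for age, 1179 to 1556 for alpha-tocopherol, 263 to 447 for both tocopherols and 0 to 79 between the supplements.

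Of the gene lists, 7, 3, 6 and 5 were called for age, alpha-tocopherol, both tocopherols and between the supplements. An estimated correlation called 0, 0, 0 and 0, fry's directional test 2, 5, 0 and 0, and its mixed test 21, 22, 15 and 10. With the mean of all probe sets of a gene, 3 were called for both tocopherols and 2 between the supplements. A stricter filter called 1, 2 and 2 lists in the last 3 comparisons. Quantile normalization called 0 for alpha-tocopherol and 0 between the supplements. Median centring called 2 for both tocopherols, and no filter 3 between the supplements. The hybridization covariate called 1, 3 and 3 and the 18S covariate 11, 11 and 3 in the last 3 comparisons. Without young control 3 and old control 3, 12 were called for age and 1 for alpha-tocopherol, and without old controls 1 and 4, 1 for alpha-tocopherol and 2 for both. Leaving out an animal gave 5 to 9, 1 to 5, 2 to 8 and 0 to 5 lists. Oxidative phosphorylation changed sign for alpha-tocopherol with quantile normalization (camera adjusted p = 0.898) and the hybridization covariate (0.0953), and between the supplements with that covariate (0.183).

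The position along the age change with alpha-tocopherol was 0.534 ± 0.280 with the 18S covariate, less than 2 standard errors above 0. On age-called probe sets from a part of the old controls a slope, another measure, was 0.285 with alpha-tocopherol and 0.247 with both tocopherols. A mean of 35.95 and 12.1 such probe sets were called with the opposite sign on the other part. Over all tested probe sets 68.45, against 386, were called by both supplements with the old controls split. Leaving out an animal gave 0.684 to 0.804 and 0.503 to 0.593. The cause of these differences was not tested.

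With the replicate number as a block, 347, 1578, 451 and 34 probe sets and 7, 3, 6 and 3 lists were called, and the positions were 0.697 and 0.526. Same-numbered samples correlated by 0.041 to 0.101 for age, with a mean of 0.072, against -0.017 for samples of other numbers. Of these 5 pairs 1 was over 0.1, and 1 of 5 samples was closest to its own number. The numbers show no strong pairing, and a weak link between same-numbered controls stays open. Dim probe sets, the lowest 40%, were not tested.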

Other observations

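Both hypotheses on fatty acid oxidation were written before the tests' results were seen, on genes whose values had not been looked at when the lists were made; the pattern itself was found on these data.

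Endothelial markers were called lower in 5 of 16 cases with alpha-tocopherol and in 3 of 16 with both tocopherols, with 0 called higher in either (6 and 4 lower adjusted over the list alone). The lists did not pass camera (adjusted p = 0.14 and 0.28). The tight junction gene Cldn5, which rose with age by 0.95 ± 0.23, fell with alpha-tocopherol (-0.95 ± 0.23) and with both tocopherols (-0.94 ± 0.23). Of 15 clock genes 2 rose and 3 fell with alpha-tocopherol, and 1 rose and 1 fell with both tocopherols. With both tocopherols the repressor Cry1 rose by 0.91 ± 0.16 and the transcription factor Dbp fell by 1.46 ± 0.30 on the log2 scale. The time of day of tissue collection is not given in the sources used here.

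A hypothesis for the lower fatty acid oxidation genes of old hearts is lower PPAR alpha or fasting signalling. Its targets outside the fatty acid oxidation list and not looked at before had a median age change of -0.42. Only 3 such genes were tested, too few to decide. A second hypothesis is lower glucocorticoid signalling. Its 15 targets had a median of -0.26 (95% bootstrap interval over genes, not animals, -1.02 to -0.137), with 3 above 0. Fkbp5 and Zbtb16, which turned out to be among the largest age changes, are 2 of them, and the 13 others had a median of -0.23 (-0.60 to -0.064), with 3 above 0; this second test was chosen after the result was seen. These targets lie outside the fatty acid oxidation list, so their fall cannot show what lowered the fatty acid oxidation genes. Lower glucocorticoid signalling stays a hypothesis, and other signals that act on these targets were not tested. The 2 hypotheses were not weighed against each other.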
